A study of Mus musculus with 12 samples.

How the data were processed

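Colon epithelial cells were scraped from the colons of C57BL/6 mice, at 18 weeks of age, and total RNA was sequenced from 12 libraries in 3 groups of 4. The groups were control, AOM/DSS and AOM/DSS with curcumin. AOM (azoxymethane) is a chemical carcinogen, and DSS (dextran sulfate sodium) is a polymer given to animals to inflame the colon. Per the labels' protocols, the proximal segment and the tumours of the right portion were taken away before scraping, and the scrapings were spun at low speed and washed to lower their content of blood cells. The labels do not say that each library comes from a separate animal, so the p-values given here measure the spread between samples.

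The deposited values are FPKM, a read count scaled to gene length and library depth, 1 column per library for 24391 gene symbols, per the file names, since the files have no header line. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.2.6, Picard, featureCounts 1.5.1, DESeq2 1.14.1 and R 3.4.0 and the genome build mm9, with no role or order for each tool. The strand setting, the annotation and any filter on genes are not stated. The deposited FPKM of a gene were whole multiples of a step set by the gene and the library, within a tolerance of 0.001, for all 19233 genes above 0 in any library. A further 5158 genes were 0 in every library. Read totals recovered from these steps ranged from 5567988 to 15968416 per library, and they count reads assigned to genes. The steps also gave the size factor of each library, which equalled the median-of-ratios factor, so median-ratio scaling hardly moves the deposited values and tests nothing. The annotation available here is of a later mouse build, so genes are given by symbol and no coordinates are printed. It was used only for GC content and exon overlap, after matching of 11964 of the 12052 tested genes (99.3%), 650 of them through an older symbol.

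Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in eBayes, Benjamini-Hochberg adjustment and a threshold of adjusted p below 0.05. Genes with FPKM of 1 or more in at least 4 libraries were kept, which left 12052. All 12 libraries entered 1 model with a mean per group and 9 residual degrees of freedom. Fold changes are differences on the log2(FPKM + 1) scale, which understates the change of low genes. The 3 comparisons were AOM/DSS minus control, curcumin minus AOM/DSS and curcumin minus control. The fold changes of the first pair of comparisons were set beside 100 simulated draws with no effect on shared AOM/DSS libraries, and their overlap beside that of independent lists. Distances between groups were tested with a one-sided exact permutation test over the 35 splits of 8 libraries, whose smallest p is 0.0286.

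The test, the libraries entered, the rule for genes named and 33 gene lists with 570 entries were fixed before the data were examined. The lists covered epithelial cell types and programmes, immune and metabolic programmes, chromatin, checks of sampling (clock, immediate early and heat shock, distal Hox and small intestine genes) and other cell types that scrapings can hold. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with estimated correlation. The rule named, for each of the first pair of comparisons, the 12 genes each way with the largest log2 fold change among those past the threshold, with all 4 libraries of one group above all 4 of the other and a mean of at least 2 FPKM. It took 5 each way for curcumin against control, the 10 genes in opposite directions whose smaller change was largest, and 13 genes whatever their values. For each list past the threshold it took up to 4 members with the largest changes, those past the threshold first. Outside the rule, Nr1d2, Cry2, Nfkbiz, Mmp14 and Car2 with curcumin were named after values were seen, as the called members behind small counts, and Arntl to set beside Dbp. A few genes that the rule took are not given here and were not replaced.

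Alternatives changed the pseudocount to 0.1 or 0.5, removed the filter or raised it to 5 FPKM, rescaled the values to a common sum or by quantiles, added the replicate number as a block, dropped the intensity trend, weighted libraries, fitted only the groups compared, required a fold of 2, or left out each library in turn. Chosen after seeing the data were a covariate for the GC group of a library, removal of the GC trend of each library over 20 bins, limma voom on the recovered reads, and fits of the GC-rich or the AT-rich libraries alone. A library was called GC-rich where its deviations from the mean of all libraries correlated positively with gene GC content across genes.

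Over 12066 simulated genes the test found 76 of 100 genes changed 2-fold and 98 of 100 changed 4-fold for AOM/DSS against control. For curcumin against AOM/DSS it found 78 and 98, with 9 unchanged genes called in either. With no change it gave 0 calls over 12077 genes in any comparison. AOM/DSS and curcumin libraries split by GC gave 1033 calls, so these rates may not hold. Read recovery was exact for 99.943% of 1763 simulated genes. With the strand setting unknown, reads of overlapping genes are hard to part: 45 of the 173 annotated genes named here share exon bases with another gene, 10 of them over more than 20% of their exon bases (Nr1i3, Mt2, Mzb1, Duoxa2, Mir6381, Akr1b7, Fdps, Ccnd1, Ube2c and Plet1os). All deposited columns were used. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.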

Results

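Messenger RNA was measured by sequencing in scraped colon epithelial cells of 18-week-old C57BL/6 mice, in 4 control libraries, 4 AOM/DSS libraries and 4 libraries from AOM/DSS with curcumin, called curcumin below. AOM is a carcinogen that, followed by colitis from DSS in the drinking water, is used to produce colon tumours in mice. The title of the series gives as its subject the transcriptome changes of colon cancer sped up by colitis, and their block by curcumin, a polyphenol of turmeric. Recovered read totals were 9849671, 5567988, 13732871, 12876137 reads in control replicates 0 to 3, 9442379, 8644331, 11655061, 14004870 in AOM/DSS and 10106013, 9375948, 15423785, 15968416 in curcumin. Between 15399 and 17127 genes per library were above 0. In "without" clauses a number after a group names the replicate, and members of a list are those tested. Values below are mean FPKM ± SD over the 4 libraries of a group, and fold changes are on the log2(FPKM + 1) scale.

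The libraries fell into groups by gene GC content. Control replicate 0, AOM/DSS replicates 0 and 1 and curcumin replicates 0 and 1 gave higher values to GC-rich genes, and the other 7 libraries to AT-rich genes. The first principal component held 24.6% of the variance, the second 19.6% and the third 12.9%, and across genes, which are not independent replicates, the loading on the first correlated with GC content at r = 0.601 in size. Mean distance between AOM/DSS and control libraries was 59.1 against 53.8 within groups, a difference of 5.35 (one-sided exact permutation p = 0.0571). Curcumin and AOM/DSS libraries lay 57.2 apart against 49.9 within groups (difference 7.30, exact permutation p = 0.0571), and curcumin and control libraries 52.3 against 47.3 (difference 5.03, exact permutation p = 0.0571). The smallest p that 35 splits allow is 0.0286.

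**Figure D1:**
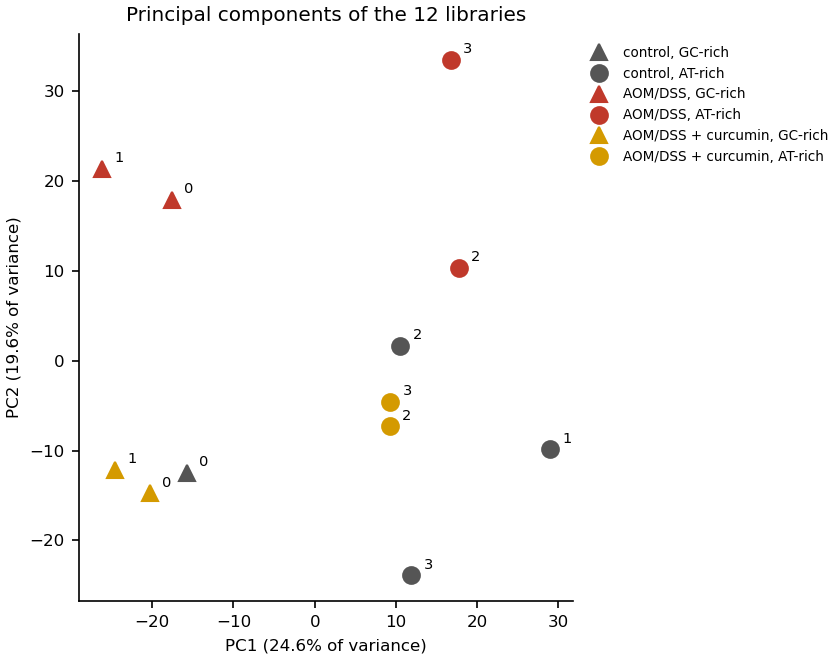
Principal components of log2(FPKM + 1) over the 12052 tested genes, with 1 point per library, colour for the group, shape for the GC group and digits for the replicate. The 5 GC-rich libraries lie at negative PC1 (24.6% of variance) and the 7 AT-rich libraries at positive PC1.

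AOM/DSS against control asks what the carcinogen and colitis changed in the colon epithelium. Cd177, a surface glycoprotein best known from neutrophils, was at 14.9 ± 3.76 FPKM in control and 148 ± 40.6 in AOM/DSS (log2 fold change 3.23, SE 0.22, adjusted p = 2.6e-05). Ceacam10 went from 15.7 ± 3.71 to 77.5 ± 16.7 (log2 fold change 2.24, SE 0.18, adjusted p = 0.000117). Plet1, a surface protein of epithelial progenitor cells, went from 3.37 ± 2.74 to 33.1 ± 6.52 (log2 fold change 3.13, SE 0.38, adjusted p = 0.00274). Plet1os, transcribed across the same locus, rose as well (2.36, adjusted p = 0.00366), but shares exon bases with Plet1, so it is uncertain. Lactoperoxidase (Lpo) rose from 1.76 ± 1.13 to 11.6 ± 1.20 (2.28, adjusted p = 0.00313), the interferon-inducible GTPase Ifi47 from 2.19 ± 0.876 to 10.8 ± 3.83 (1.87, adjusted p = 0.00435), and creatine kinase B (Ckb) from 1.28 ± 0.328 to 7.21 ± 3.14 (1.78, adjusted p = 0.00366). E2f2, a transcription factor of the cell cycle, rose by 1.71 (adjusted p = 0.00922) and Pmepa1, a membrane protein, by 1.47 (adjusted p = 0.00994). The other rises named by the rule were Slpi, a secreted protease inhibitor (2.01, adjusted p = 0.0493), the secretoglobin Scgb1b3 (1.91, adjusted p = 0.04) and Duoxa2, the maturation factor of the oxidase Duox2 (1.59, adjusted p = 0.0434). Duoxa2 shares 42.8% of its exon bases with Duoxa1 on the opposite strand, so it is uncertain.

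Genes of ion and nutrient handling were among the falls. S100g, the calcium-binding protein calbindin-D9k, went from 151 ± 39.5 FPKM to 26.4 ± 11.6 (log2 fold change -2.54, SE 0.33, adjusted p = 0.00366). Slc26a3, the chloride/bicarbonate exchanger of the colon surface, went from 624 ± 111 to 217 ± 72.8 (log2 fold change -1.57, SE 0.22, adjusted p = 0.00433). Fxyd4, a regulator of the sodium pump, went from 226 ± 63.7 to 49.9 ± 21.6 (log2 fold change -2.23, SE 0.34, adjusted p = 0.00767). The colonic proton/potassium pump Atp12a fell from 314 ± 84.95 to 102 ± 49.03 (-1.70, adjusted p = 0.0295), the peptide transporter Slc15a1 from 139 ± 27.2 to 45.1 ± 12.7 (-1.63, adjusted p = 0.00274) and the sugar phosphate transporter Slc37a2 from 149 ± 64.03 to 28.1 ± 11.5 (-2.38, adjusted p = 0.00771). Clock-driven transcription factors fell too, among them Dbp, from 70.99 ± 27.5 to 12.2 ± 10.5 (-2.78, adjusted p = 0.0223), Tef, from 57.03 ± 12.3 to 16.02 ± 9.0 (-1.90, adjusted p = 0.00908), and the clock repressor Ciart, from 21.1 ± 8.93 to 2.93 ± 2.66 (-2.63, adjusted p = 0.00771). The chitinase Chit1 (-1.91, adjusted p = 0.00419), the cytochrome P450 Cyp2d12 (-1.85, adjusted p = 0.0105) and the connexin Gjb5 (-1.60, adjusted p = 0.0099) completed the 12.

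**Figure D2:**
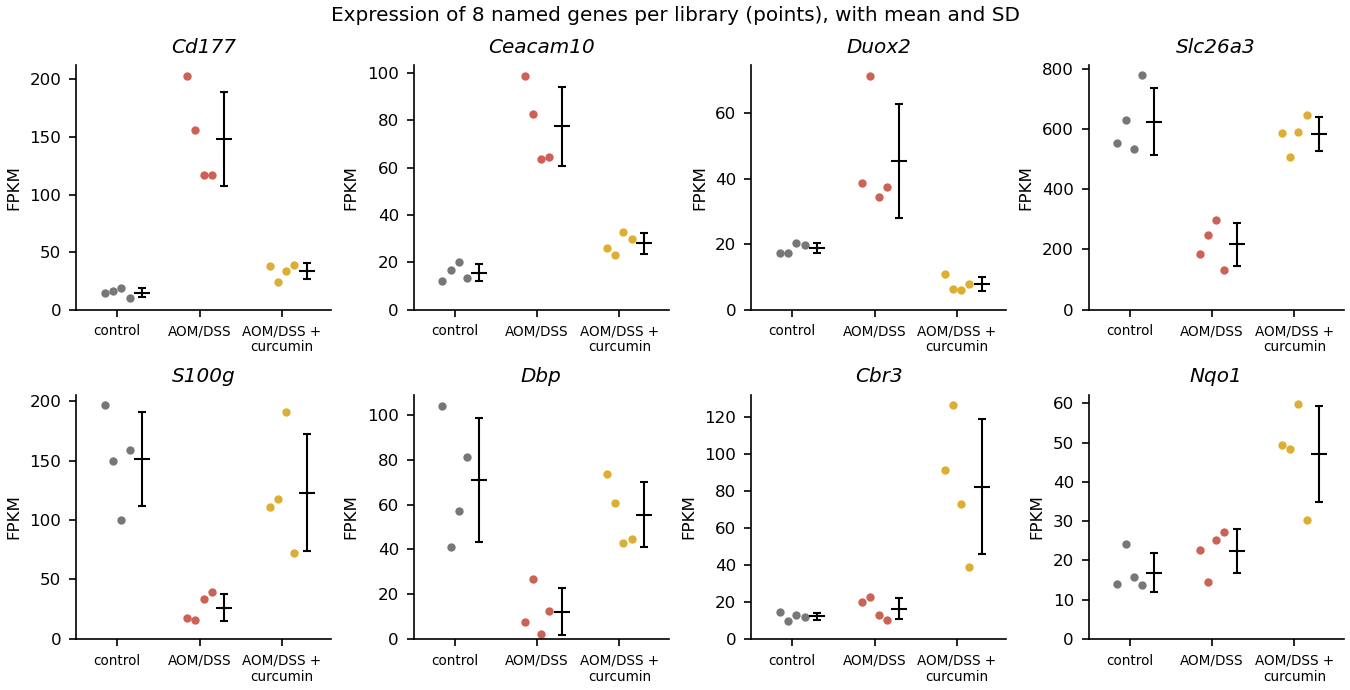
FPKM of 8 genes in each of the 12 libraries (points), with the group mean and SD beside them (bars), on linear axes from 0. Cd177 lies between 117 and 203 FPKM in the 4 AOM/DSS libraries and at or below 38.4 FPKM in the other 8.

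Among the epithelial lists, colonocyte genes fell (median log2 fold change -0.29, camera adjusted p = 2.62e-05). For colonocytes this p was 0.613 with estimated correlation, and the median -0.18 without control 1 and -0.51 without AOM/DSS 2. Of its 23 members, 0 rose and 4 fell over all genes, against 0 and 8 over the list alone. Those past the threshold over all genes were Slc26a3, the phosphate transporter Slc20a1 (189.8 ± 69.1 to 62.7 ± 18.6 FPKM, -1.56, adjusted p = 0.0123) and the carbonic anhydrases Car2 (962 ± 76.3 to 455 ± 89.8, -1.09, adjusted p = 0.00433) and Car4 (1089 ± 86.5 to 532 ± 130.4, -1.06, adjusted p = 0.0358), while Car1, at 1350.5 ± 759.9 and 978 ± 840.3, did not pass (-0.65, adjusted p = 0.605). Goblet cell genes rose (median log2 fold change 0.35, camera adjusted p = 0.00387), with 1 of 16 past the threshold over all genes and 5 over the list alone. For goblet cells this p was 0.613 with estimated correlation, and the median 0.22 without AOM/DSS 0. That gene was Spink4 (572 ± 189 to 1348 ± 263 FPKM, 1.28, adjusted p = 0.014), and Muc2, the main secreted mucin, was at 217 ± 22.2 and 425 ± 154 (0.90, adjusted p = 0.083). Retnlb (2.64, adjusted p = 0.196), Spdef (0.93, adjusted p = 0.152) and Ang4 (0.91, adjusted p = 0.687) did not pass. Car4 (9 of 12 leave-outs, adjusted p up to 0.134) and Spink4 (without control 3, adjusted p up to 0.0537) lost the call without 1 library.

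Cell cycle genes rose as a list (median log2 fold change 0.78, camera adjusted p = 1.04e-08), with 27 of 28 above control in mean and 0 past the threshold, over all genes or over the list alone. For cell cycle this p was 0.613 with estimated correlation. Mki67, the proliferation marker, was at 7.89 ± 4.35 FPKM in control and 13.6 ± 4.39 in AOM/DSS (0.81, adjusted p = 0.343), Ccnb1 at 4.32 ± 2.33 and 10.6 ± 4.66 (1.143, adjusted p = 0.139) and Cdk1 at 5.61 ± 5.02 and 11.2 ± 4.83 (1.09, adjusted p = 0.3). Aurkb (1.09, adjusted p = 0.249) and Ube2c (1.143, adjusted p = 0.295) gave similar sizes. Wnt targets rose (median log2 fold change 0.31, camera adjusted p = 0.00594), with 0 of 13 past the threshold over all genes and 4 over the list alone. For Wnt targets this p was 0.613 with estimated correlation, and the median 0.50 without control 0 and 0.11 without control 1. Without control 1 or AOM/DSS 3 the call ended (adjusted p = 0.166 and 0.0538). In the GC-rich libraries alone, a later fit, Wnt targets did not rise (median -0.24, adjusted p = 0.35, 3.59e-05 to 0.613 over alternatives). Cd44 (1.09, adjusted p = 0.0969), Tcf7 (0.77, adjusted p = 0.224), Ephb2 (0.62, adjusted p = 0.133) and Ccnd1 (0.57, adjusted p = 0.191) had its largest changes, while the stem cell marker Lgr5 (-0.34, adjusted p = 0.64) and the feedback regulator Axin2 (0.53, adjusted p = 0.425) did not pass. The regenerative or fetal-like list rose (median log2 fold change 0.70, camera adjusted p = 0.023). For the regenerative list this p was 0.613 with estimated correlation. Without control 0 or AOM/DSS 1 or 3 the call ended (adjusted p = 0.185, 0.143 and 0.0667). Of its 10 members, 1 rose and 0 fell over all genes, against 3 and 1 over the list alone. The riser was Cyr61, a YAP target (1.04 ± 0.529 to 2.76 ± 0.326 FPKM, 0.91, adjusted p = 0.0275), and Clu (1.11, adjusted p = 0.559), Sprr1a (0.95, adjusted p = 0.37) and Hbegf (0.88, adjusted p = 0.157) did not pass. Cyr61 (6 of 12 leave-outs, adjusted p up to 0.0976) lost the call without 1 library.

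Genes of epithelial antimicrobial defence rose (median log2 fold change 1.02, camera adjusted p = 0.00344). For antimicrobial defence this p was 0.613 with estimated correlation, and the median 0.49 without control 0. Of its 15 members, 4 rose and 0 fell over all genes, against 6 and 2 over the list alone. They were Duox2, an oxidase that releases hydrogen peroxide (18.8 ± 1.53 to 45.5 ± 17.4 FPKM, 1.17, adjusted p = 0.0218), Duoxa2, Slpi and Nos2, the inducible nitric oxide synthase (1.22 ± 0.749 to 4.06 ± 1.03, 1.22, adjusted p = 0.0315). Interferon response genes rose as a list (median log2 fold change 0.46, camera adjusted p = 0.000235), with all 18 members higher in mean and 0 past the threshold in either adjustment. For interferon response this p was 0.613 with estimated correlation, and the median 0.26 without AOM/DSS 3. AOM/DSS replicate 3 held the top value of Ifit1 (26.9 FPKM, 1.32, adjusted p = 0.253), Ifit2 (1.06, adjusted p = 0.422), Usp18 (1.01, adjusted p = 0.288) and Isg15 (0.88, adjusted p = 0.289). In the GC-rich libraries alone, a fit with 1 control chosen after seeing the data, interferon response did not rise (median -0.0686, adjusted p = 0.218, 6.13e-11 to 0.613 over alternatives). Antigen presentation genes rose as a list (median log2 fold change 0.67, camera adjusted p = 0.00115), with all 12 members higher in mean and 0 past the threshold in either adjustment. For antigen presentation this p was 0.613 with estimated correlation, and the median 0.42 without AOM/DSS 2. Cd74 was at 87.4 ± 59.4 and 164 ± 98.05 FPKM (0.96, adjusted p = 0.384), with H2-Ab1 (0.91, adjusted p = 0.446), H2-DMb1 (0.91, adjusted p = 0.269) and H2-DMa (0.83, adjusted p = 0.344) next. AOM/DSS replicate 2 was the highest library for this list (1.03 from the mean of all libraries) and for B and plasma cells (1.93), and cell content was not tested as a cause. In the GC-rich libraries alone the antigen presentation list fell (median -0.49, adjusted p = 0.00146, 9.42e-09 to 0.613 over alternatives). The cytokines Tnf (0.404 ± 0.166 and 1.17 ± 0.967 FPKM) and Il1b (0.271 ± 0.245 and 1.22 ± 1.16) and the prostaglandin synthase Ptgs2 (0.0102 ± 0.0120 and 0.116 ± 0.139) lay below the filter and were not tested, and Il6 was listed at 0 in every library. Duox2 (without control 0, 1 or 3, adjusted p up to 0.0642) and Nos2 (6 of 12 leave-outs, adjusted p up to 0.0802) lost the call without 1 library.

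Circadian clock genes fell as a list (median log2 fold change -0.88, camera adjusted p = 2.08e-07). For circadian clock this p was 0.0516 with estimated correlation. Of its 14 members, 0 rose and 6 fell over all genes, against 2 and 10 over the list alone. Past the threshold were Dbp, Ciart and Tef, with Per3 (10.8 ± 4.33 to 3.10 ± 1.56 FPKM, -1.53, adjusted p = 0.0354), Nr1d2 (-1.34, adjusted p = 0.00366) and Cry2 (-0.79, adjusted p = 0.0133), while Arntl, the activator that peaks opposite to Dbp, was at 8.33 ± 2.28 and 17.6 ± 8.95 FPKM (0.90, adjusted p = 0.196). Immediate early and heat shock genes rose as a list (median log2 fold change 0.91, camera adjusted p = 3.66e-07), all 16 members being higher in mean, 0 past the threshold over all genes and 9 over the list alone. For the immediate early list this p was 0.0961 with estimated correlation. Hsph1 was at 13.6 ± 6.41 and 51.8 ± 37.6 FPKM (1.62, adjusted p = 0.155), Fosb at 3.09 ± 1.39 and 12.4 ± 11.2 (1.36, adjusted p = 0.225), and AOM/DSS replicate 0 set the means of the chaperones Hspa1a (214 FPKM, 3.00, adjusted p = 0.209) and Hspa1b (289.8 FPKM, 2.69, adjusted p = 0.25). Distal colon Hox genes fell as a list (median log2 fold change -0.39, camera adjusted p = 0.0453), with 0 of 7 past the threshold in either adjustment. For distal colon Hox genes this p was 0.649 with estimated correlation, and the median -0.12 without AOM/DSS 3. Without control 0, 1 or 3, AOM/DSS 2 or 3 or curcumin 0 the call ended (adjusted p = 0.114, 0.0596, 0.0774, 0.114, 0.684 and 0.0543). In the GC-rich libraries alone, a later fit, the distal colon Hox genes did not fall (median 0.13, adjusted p = 0.83, 4.12e-05 to 0.83 over alternatives). Hoxd13 was at 43.95 ± 10.1 and 29.4 ± 11.9 FPKM (-0.66, adjusted p = 0.342), with Hoxd10 (-0.75, adjusted p = 0.464), Hoxd11 (-0.51, adjusted p = 0.552) and Hoxa13 (-0.39, adjusted p = 0.542) alongside. Per3 (8 of 12 leave-outs, adjusted p up to 0.137) and Cry2 (without control 3, adjusted p up to 0.0576) lost the call without 1 library.

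Genes of macrophages and dendritic cells rose as a list (median log2 fold change 0.52, camera adjusted p = 0.0453), with 0 of 9 past the threshold over all genes and 1 lower over the list alone. For macrophage genes this p was 0.649 with estimated correlation, and the median 0.33 without control 3 and 0.32 without AOM/DSS 3. The call ended without control 0, 1 or 3 or AOM/DSS 2 or 3 (adjusted p = 0.0652, 0.0596, 0.222, 0.168 and 0.221). It also ended in the GC-rich libraries alone, a later fit (macrophages, median 0.0306, adjusted p = 0.87, 0.000414 to 0.87 over alternatives). C1qa was at 1.21 ± 0.702 and 3.45 ± 2.13 FPKM (0.94, adjusted p = 0.303), C1qc (0.72, adjusted p = 0.281) and Fcer1g (0.55, adjusted p = 0.395) were also higher in mean, and Ctss, a cathepsin, was at 432 ± 45.6 and 288 ± 50.6 (-0.60, adjusted p = 0.0953). The other tested lists did not pass, with median log2 fold change and camera adjusted p of enteroendocrine cells (0.035, 0.502), tuft cells (0.061, 0.221) and inflammatory cytokines and mediators (0.17, 0.393). Beside these were NF-kappaB targets (-0.11, 0.495), Nrf2 targets (0.048, 0.399), xenobiotic metabolism (-0.18, 0.0977) and fatty acid oxidation (-0.12, 0.0581). The remaining ones were cholesterol synthesis (-0.17, 0.502) and DNA methylation machinery (-0.11, 0.675). Beside these were small intestine enterocytes (-0.31, 0.289), fibroblasts (0.20, 0.405) and smooth muscle (0.072, 0.221). Beside these were B and plasma cells (0.29, 0.22), T and NK cells (0.18, 0.132) and red blood cells (-0.15, 0.544). In the DNA methylation list the median and the test pointed down and the mean, 0.075, up. Of the lists that did not pass, the cytokine list had 1 member past the threshold, Nos2. Lists with fewer than 5 members, given as members and median log2 fold change with no test, were matrix remodelling (3, 0.74), endothelium (2, -0.24), neutrophils (2, 0.63), mast cells (4, 0.35), enteric neurons and glia (1, -0.47) and adipocytes (3, 0.17), among them Mmp14, a membrane-bound matrix protease (0.74, adjusted p = 0.0469). Mmp14 (11 of 12 leave-outs, adjusted p up to 0.134) lost the call without 1 library.

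In all, 55 genes were higher and 98 lower in AOM/DSS than in control by limma, of 12052 tested (1.27%), and 1622 had an unadjusted p below 0.05. Over all tested genes, which are not independent, the libraries of both groups did not overlap for 725 (6.02%), where chance alone gives 2.86%. Within the AT-rich and the GC-rich libraries, the last with 1 control, Cd177 changed by 2.92 and 3.55 and S100g by -1.86 and -3.49. With a GC covariate the counts were 86 and 152, with array weights 98 and 190, and with only the 8 libraries compared 21 and 33. Of the 24 genes named by the rule, 19 stayed past the threshold whichever single library was left out. The calls that ended were Dbp without control 0 or 3 or AOM/DSS 0 (adjusted p up to 0.0846), and, by number of the 12 libraries whose removal ended the call, Slpi in 10 of 12 (up to 0.134), Duoxa2 in 10 of 12 (up to 0.137), Scgb1b3 in 8 of 12 (up to 0.105) and Atp12a in 5 of 12 (up to 0.116).

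Curcumin against AOM/DSS asks which expression differed when curcumin was added. Metallothionein genes rose, Mt2 from 68.7 ± 51.8 FPKM to 434 ± 165 (log2 fold change 2.88, SE 0.57, adjusted p = 0.0305) and Mt1 from 155 ± 73.2 to 697 ± 364 (log2 fold change 2.103, SE 0.46, adjusted p = 0.0481). Cbr3, a carbonyl reductase, went from 16.4 ± 5.82 to 82.3 ± 36.3 (log2 fold change 2.202, SE 0.31, adjusted p = 0.00603), Akr1b8, an aldo-keto reductase, from 45.4 ± 10.4 to 181 ± 28.8 (log2 fold change 1.98, SE 0.26, adjusted p = 0.0037), and the secreted protein Tsku from 7.62 ± 1.81 to 33.5 ± 7.76 (log2 fold change 2.00, SE 0.23, adjusted p = 0.00173). Aqp8, the water channel of colonocytes, rose from 244 ± 69.8 to 922 ± 271 (1.92, adjusted p = 0.00341) and Creb3l3, a transcription factor, from 3.26 ± 1.97 to 14.7 ± 7.31 (1.89, adjusted p = 0.0487). S100g rose to 123 ± 49.4 (2.19, adjusted p = 0.00857), Slc37a2 to 96.3 ± 24.6 (1.82, adjusted p = 0.0304), Cyp2d12 to 95.6 ± 20.3 (2.16, adjusted p = 0.00536), Dbp to 55.5 ± 14.6 (2.47, adjusted p = 0.0365) and Ciart to 17.2 ± 4.12 (2.42, adjusted p = 0.0141). Mt2 shares exon bases with a gene on the opposite strand, so its value is uncertain by whatever reads that gene adds.

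Oxidant-producing enzymes were among the largest falls with curcumin. Duox2 went from 45.5 ± 17.4 FPKM to 7.77 ± 2.16 (log2 fold change -2.37, SE 0.22, adjusted p = 0.000801), its partner Duoxa2, uncertain for its overlap with Duoxa1, from 42.8 ± 17.8 to 9.07 ± 6.46 (log2 fold change -2.21, SE 0.34, adjusted p = 0.00933) and Nos2 from 4.06 ± 1.03 to 0.320 ± 0.263 (log2 fold change -1.94, SE 0.24, adjusted p = 0.00341). Cd177 fell to 33.6 ± 6.83 (log2 fold change -2.09, SE 0.22, adjusted p = 0.000944) and Ceacam10 to 28.04 ± 4.33 (-1.42, adjusted p = 0.00341). The heat shock protein Hsph1 fell to 7.42 ± 2.44 (-2.36, adjusted p = 0.0423), Ifi47 to 2.57 ± 0.957 (-1.71, adjusted p = 0.00933), E2f2 to 1.75 ± 0.333 (-1.60, adjusted p = 0.015), Pmepa1 to 3.08 ± 0.218 (-1.50, adjusted p = 0.0113) and Ckb to 2.41 ± 0.681 (-1.21, adjusted p = 0.0305). The adhesion receptor Adgrf1 fell from 7.56 ± 3.28 to 2.21 ± 0.427 (-1.34, adjusted p = 0.0202), and Mir6381 (-1.50, adjusted p = 0.0222) is uncertain because it had 3 or 4 reads per AOM/DSS library and 0 to 2 with curcumin, and 27.6% of its exon bases overlap Gbp2.

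Nrf2 antioxidant genes, which respond to electrophiles, rose as a list with curcumin (median log2 fold change 0.36, camera adjusted p = 1.31e-08). For Nrf2 antioxidant genes this p was 0.101 with estimated correlation, and the median 0.24 without AOM/DSS 2. Of its 27 members, 2 rose and 0 fell over all genes, against 8 and 0 over the list alone. Past the threshold were Cbr3 and Gclc, of glutathione synthesis (21.8 ± 3.57 to 44.5 ± 14.99 FPKM, 0.96, adjusted p = 0.0284), while Nqo1 was at 22.5 ± 5.68 and 47.1 ± 12.3 (1.03, adjusted p = 0.0647), Gsta1 at 25.5 ± 8.66 and 38.8 ± 9.998 (0.61, adjusted p = 0.307) and Hmox1 at 2.41 ± 1.07 and 3.26 ± 0.509 (0.36, adjusted p = 0.485). Xenobiotic metabolism genes rose (median log2 fold change 0.47, camera adjusted p = 1.45e-07). For xenobiotic metabolism this p was 0.249 with estimated correlation, and the median 0.26 without AOM/DSS 1 and 0.84 without AOM/DSS 3. Of its 26 members, 4 rose and 0 fell over all genes, against 7 and 0 over the list alone. They were the efflux pump Abcb1a (87.98 ± 25.2 to 234 ± 24.0, 1.44, adjusted p = 0.0126), the nuclear receptor Nr1i3 (1.36, adjusted p = 0.0155), which overlaps Tomm40l over 74.9% of its exon bases and is uncertain, and the carboxylesterases Ces2a (1.32, adjusted p = 0.017) and Ces2c (1.29, adjusted p = 0.0186). Cyp1a1, the target of the aryl hydrocarbon receptor, lay below the filter at 0.0180 ± 0.0360 and 0.00540 ± 0.0108 FPKM and was not tested. Genes of fatty acid oxidation and PPAR targets rose (median log2 fold change 0.33, camera adjusted p = 2.25e-07), with 1 of 21 past the threshold over all genes and 5 over the list alone. For fatty acid oxidation this p was 0.249 with estimated correlation. That gene was the carnitine carrier Slc25a20 (139.6 ± 30.1 to 234 ± 26.5 FPKM, 0.77, adjusted p = 0.0352), beside Angptl4 (0.81, adjusted p = 0.344) and Fabp2 (0.69, adjusted p = 0.608). Cholesterol synthesis genes rose as a list (median log2 fold change 0.40, camera adjusted p = 1.55e-05), with 15 of 17 above AOM/DSS in mean and 0 past the threshold in either adjustment, Insig1 (0.95, adjusted p = 0.212), Msmo1 (0.61, adjusted p = 0.195), Lss (0.58, adjusted p = 0.167) and Sqle (0.58, adjusted p = 0.221) leading. For cholesterol synthesis this p was 0.249 with estimated correlation. Gclc (4 of 12 leave-outs, adjusted p up to 0.0781), Nr1i3 (without curcumin 0, 1 or 2, adjusted p up to 0.0536), Ces2a (without curcumin 0 or 2, adjusted p up to 0.0634), Ces2c (without curcumin 0 or 2, adjusted p up to 0.0674) and Slc25a20 (8 of 12 leave-outs, adjusted p up to 0.113) lost the call without 1 library.

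Colonocyte genes rose with curcumin (median log2 fold change 0.36, camera adjusted p = 7.27e-06). For colonocytes this p was 0.249 with estimated correlation, and the median 0.24 without curcumin 0. Of its 23 members, 5 rose and 0 fell over all genes, against 5 and 0 over the list alone. They were Aqp8, Slc26a3 (217 ± 72.8 to 582 ± 56.97 FPKM, 1.48, adjusted p = 0.00792), Slc20a1 (62.7 ± 18.6 to 190.5 ± 26.6, 1.63, adjusted p = 0.0119), Car4 (532 ± 130.4 to 1139 ± 379.9, 1.08, adjusted p = 0.0317) and Car2 (455 ± 89.8 to 866 ± 83.5, 0.94, adjusted p = 0.0126), with Car1 at 978 ± 840.3 and 1659 ± 234 (1.10, adjusted p = 0.311). Lists of 6 other cell types fell in this comparison, 0 of them past the threshold with estimated correlation, and cell content was not tested as the cause of the colonocyte rise. Enteroendocrine genes rose as a list (median log2 fold change 0.39, camera adjusted p = 0.0433), with 0 of 13 past the threshold in either adjustment. For enteroendocrine cells this p was 0.382 with estimated correlation, and the median 0.20 without AOM/DSS 2. Without AOM/DSS 1 or 2 or curcumin 0, 2 or 3 the call ended (adjusted p = 0.177, 0.421, 0.116, 0.0633 and 0.0766). Insl5 was at 42.8 ± 15.98 and 109 ± 31.4 FPKM (1.35, adjusted p = 0.195), Gcg at 15.3 ± 7.77 and 37.3 ± 13.5 (1.28, adjusted p = 0.18), Pyy at 91.98 ± 37.1 and 148 ± 66.4 (0.72, adjusted p = 0.52), and Tac1 at 17.04 ± 17.05 and 4.71 ± 0.983 (-1.30, adjusted p = 0.231). Small intestine enterocyte genes rose as a list (median log2 fold change 0.21, camera adjusted p = 0.0341), with the retinol-binding protein Rbp2, 29.7 ± 5.003 to 91.3 ± 16.5 FPKM (1.58, adjusted p = 0.00338), as its 1 of 6 members past the threshold in either adjustment. For small intestine enterocytes this p was 0.249 with estimated correlation, and the median 0.12 without AOM/DSS 1, 0.40 without AOM/DSS 3, 0.34 without curcumin 1 and 0.14 without curcumin 2. It ended without AOM/DSS 0 or 1 or curcumin 2 (adjusted p = 0.0848, 0.177 and 0.0764), and Slc10a2 (-0.59, adjusted p = 0.788), Apob (0.41, adjusted p = 0.59) and Mttp (0.26, adjusted p = 0.458) did not pass. Car4 (7 of 12 leave-outs, adjusted p up to 0.0823) lost the call without 1 library.

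Defence and inflammation lists fell with curcumin. Antimicrobial genes fell (median log2 fold change -1.61, camera adjusted p = 0.000295), with Duox2, Duoxa2 and Nos2 as the 3 of 15 past the threshold, against 5 lower and 2 higher over the list alone. For antimicrobial defence this p was 0.249 with estimated correlation, and the median -0.65 without AOM/DSS 3. Reg3b (-3.07, adjusted p = 0.562) varied from 0 to 267 FPKM among curcumin libraries. The cytokine list fell (median log2 fold change -0.43, camera adjusted p = 0.0236), with Nos2 as the 1 of 5 members past the threshold in either adjustment, and Ccl5 (-0.67, adjusted p = 0.257), Cxcl5 (-0.43, adjusted p = 0.79) and Ccl20 (-0.15, adjusted p = 0.93) did not pass. For cytokines this p was 0.249 with estimated correlation, and the median -0.85 without AOM/DSS 0 and -0.27 without AOM/DSS 3. Its call ended without AOM/DSS 1, 2 or 3 (adjusted p = 0.0681, 0.0564 and 0.0943). Untested below the filter, Tnf was at 1.17 ± 0.967 FPKM in AOM/DSS and 0.229 ± 0.135 with curcumin, Il1b at 1.22 ± 1.16 and 0.114 ± 0.0871, and Ptgs2 at 0.116 ± 0.139 and 0.0112 ± 0.0224. Antigen presentation genes fell as a list (median log2 fold change -0.82, camera adjusted p = 2.98e-05), with 0 of 12 past the threshold over all genes and 5 lower over the list alone. For antigen presentation this p was 0.249 with estimated correlation. Cd74 was at 164 ± 98.05 and 53.01 ± 21.04 FPKM (-1.54, adjusted p = 0.144), beside H2-Eb1 (-1.54, adjusted p = 0.15), H2-Aa (-1.44, adjusted p = 0.158) and H2-Ab1 (-1.19, adjusted p = 0.276). Lists of B and plasma cells and of macrophages and dendritic cells fell as well, neither past the threshold with estimated correlation and the first not without AOM/DSS 2. AOM/DSS replicate 2 was highest for both antigen presentation and B and plasma cells. Whether cell content made the fall was not tested. Interferon genes fell as a list (median log2 fold change -0.41, camera adjusted p = 0.00302), with 0 of 18 past the threshold in either adjustment. For interferon response this p was 0.382 with estimated correlation, and the median -0.094 without AOM/DSS 3 and -0.27 without curcumin 1. Without AOM/DSS 3 the call ended (adjusted p = 0.288). Its largest changes were Zbp1 (-1.02, adjusted p = 0.131), Ifit2 (-0.75, adjusted p = 0.569), Gbp2 (-0.73, adjusted p = 0.497) and Oasl2 (-0.68, adjusted p = 0.311).

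Cell cycle genes fell as a list with curcumin (median log2 fold change -0.52, camera adjusted p = 1.69e-05), with 0 of 28 past the threshold in either adjustment, and Mki67 was at 9.30 ± 3.22 FPKM (-0.50, adjusted p = 0.573). For cell cycle this p was 0.382 with estimated correlation, and the median -0.34 without AOM/DSS 1. Top2a (-0.75, adjusted p = 0.442), Bub1b (-0.72, adjusted p = 0.318), Ccna2 (-0.69, adjusted p = 0.381) and Ube2c (-0.72, adjusted p = 0.517) had larger falls in mean. Lgr5 (0.33, adjusted p = 0.636), Axin2 (-0.66, adjusted p = 0.276) and Muc2 (0.10, adjusted p = 0.902) did not pass. The regenerative or fetal-like list fell (median log2 fold change -0.36, camera adjusted p = 0.00302). For the regenerative list this p was 0.249 with estimated correlation, and the median -0.59 without curcumin 0. Of its 10 members, 0 rose and 1 fell over all genes, against 0 and 3 over the list alone. Cyr61 was the 1 that fell (2.76 ± 0.326 to 0.853 ± 0.196 FPKM, -1.02, adjusted p = 0.0157), with Clu (-2.38, adjusted p = 0.158), Hbegf (-1.13, adjusted p = 0.0694) and Ly6a (-0.62, adjusted p = 0.449) short of the threshold. Clock genes rose as a list (median log2 fold change 0.79, camera adjusted p = 0.000174), and 5 of 14 rose and 1 fell over all genes, against 7 and 1 over the list alone. For circadian clock this p was 0.119 with estimated correlation. Dbp, Ciart, Tef (16.02 ± 9.0 to 46.03 ± 4.50 FPKM, 1.62, adjusted p = 0.022), Nr1d2 (1.01, adjusted p = 0.0181) and Cry2 (0.79, adjusted p = 0.0149) rose, and Npas2, a partner-type activator of the clock, fell (8.61 ± 2.53 to 3.44 ± 1.06, -1.11, adjusted p = 0.02). Immediate early and heat shock genes fell as a list (median log2 fold change -0.97, camera adjusted p = 5.91e-10), with 2 of 16 past the threshold over all genes and 13 over the list alone. For the immediate early list this p was 0.06 with estimated correlation. The 2 were Hsph1 and the orphan receptor Nr4a1 (5.48 ± 2.18 to 1.74 ± 0.456, -1.19, adjusted p = 0.0317), while Hspa1a (-2.81, adjusted p = 0.226) and Hspa1b (-2.70, adjusted p = 0.228), highest in AOM/DSS replicate 0, did not pass. Cyr61 (without curcumin 0 or 1, adjusted p up to 0.0546), Tef (5 of 12 leave-outs, adjusted p up to 0.0694), Nr1d2 (without curcumin 1, 2 or 3, adjusted p up to 0.0634), Cry2 (without curcumin 1, adjusted p up to 0.0532), Npas2 (without curcumin 1, 2 or 3, adjusted p up to 0.0718) and Nr4a1 (7 of 12 leave-outs, adjusted p up to 0.11) lost the call without 1 library.

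Several lists of other cell types fell with curcumin, with 0 members of these lists past the threshold over all genes. Macrophage and dendritic cell genes fell as a list (median log2 fold change -1.02, camera adjusted p = 0.000295), with 6 of 9 lower and 1 higher over the list alone and Lyz2 at 25.6 ± 13.8 and 7.94 ± 8.53 FPKM (-1.81, adjusted p = 0.216). For macrophage genes this p was 0.249 with estimated correlation. C1qa (-1.13, adjusted p = 0.196), C1qb (-1.06, adjusted p = 0.253) and Fcer1g (-1.03, adjusted p = 0.089) followed. B and plasma cell genes fell (median log2 fold change -0.78, camera adjusted p = 0.00152), with 0 of 10 over the list alone, and Jchain was at 17.6 ± 23.7 and 2.62 ± 3.92 FPKM (-2.104, adjusted p = 0.315), with Cd79a (-1.22, adjusted p = 0.463), Pax5 (-1.04, adjusted p = 0.465) and Mzb1 (-0.99, adjusted p = 0.226) beside it. For B and plasma cells this p was 0.306 with estimated correlation, and the median -0.31 without AOM/DSS 2 and -1.20 without AOM/DSS 3. Without AOM/DSS 2 the call ended (adjusted p = 0.127). T and NK cell genes fell (median log2 fold change -0.44, camera adjusted p = 0.00449; 2 of 7 over the list alone), led by Cd3g (-0.80, adjusted p = 0.191), Cd2 (-0.64, adjusted p = 0.409), Lck (-0.51, adjusted p = 0.2) and Cd3e (-0.44, adjusted p = 0.503). For T and NK cells this p was 0.249 with estimated correlation. Fibroblast genes fell (median log2 fold change -0.86, camera adjusted p = 0.00265; 2 of 8 over the list alone), with Sparc at 3.89 ± 5.06 (AOM/DSS replicate 3 at 11.4) and 0.660 ± 0.407 (-1.12, adjusted p = 0.374), Col3a1 (-1.07, adjusted p = 0.415), Dcn (-0.92, adjusted p = 0.477) and Fbln1 (-0.89, adjusted p = 0.158). For fibroblasts this p was 0.249 with estimated correlation, and the median -0.49 without AOM/DSS 3. Smooth muscle genes fell (median log2 fold change -0.56, camera adjusted p = 0.00787; 0 of 6 over the list alone). For smooth muscle this p was 0.249 with estimated correlation. Without AOM/DSS 3 the call ended (adjusted p = 0.068). Acta2 was at 2.24 ± 2.85 and 0.252 ± 0.308 FPKM (-1.06, adjusted p = 0.357), Myl9 (-1.01, adjusted p = 0.342), Actg2 (-0.72, adjusted p = 0.336) and Smtn (-0.40, adjusted p = 0.381).

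Globin genes of red blood cells fell as a list with curcumin (median log2 fold change -1.44, camera adjusted p = 0.00302), with 0 of 5 past the threshold in either adjustment. For red blood cells this p was 0.291 with estimated correlation, and the median -2.32 without AOM/DSS 0 and -0.89 without AOM/DSS 1. Without AOM/DSS 1 the call ended (adjusted p = 0.0509). Hbb-b1 was at 42.4 ± 34.4 and 9.56 ± 1.48 FPKM (-1.44, adjusted p = 0.415), with Hba-a1 (-1.64, adjusted p = 0.283), Hba-a2 (-1.64, adjusted p = 0.282) and Hbb-b2 (-1.29, adjusted p = 0.488), which are near-identical copies, so their single values are uncertain. The other tested lists did not pass, with median log2 fold change and camera adjusted p of Wnt targets (-0.19, 0.0781), goblet cells (0.011, 0.546) and tuft cells (0.047, 0.974). Beside these were NF-kappaB targets (-0.16, 0.0751), DNA methylation machinery (0.026, 0.638) and distal colon Hox genes (0.26, 0.157). The NF-kappaB list had 1 of 13 members past the threshold, Nfkbiz (16.1 ± 4.96 to 6.38 ± 0.836 FPKM, -1.17, adjusted p = 0.0257), a nuclear co-regulator. The mean of the goblet list was -0.077, below 0, while its median and test pointed up, and the mean of the DNA methylation list, -0.078, and its test pointed down with a median above 0. Lists with too few members for a test, given as members and median log2 fold change, were matrix remodelling (3, -0.089), endothelium (2, 0.0079), neutrophils (2, -0.71), mast cells (4, -0.30), enteric neurons and glia (1, 0.12) and adipocytes (3, 0.21). Nfkbiz (6 of 12 leave-outs, adjusted p up to 0.0856) lost the call without 1 library.

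**Figure D3:**
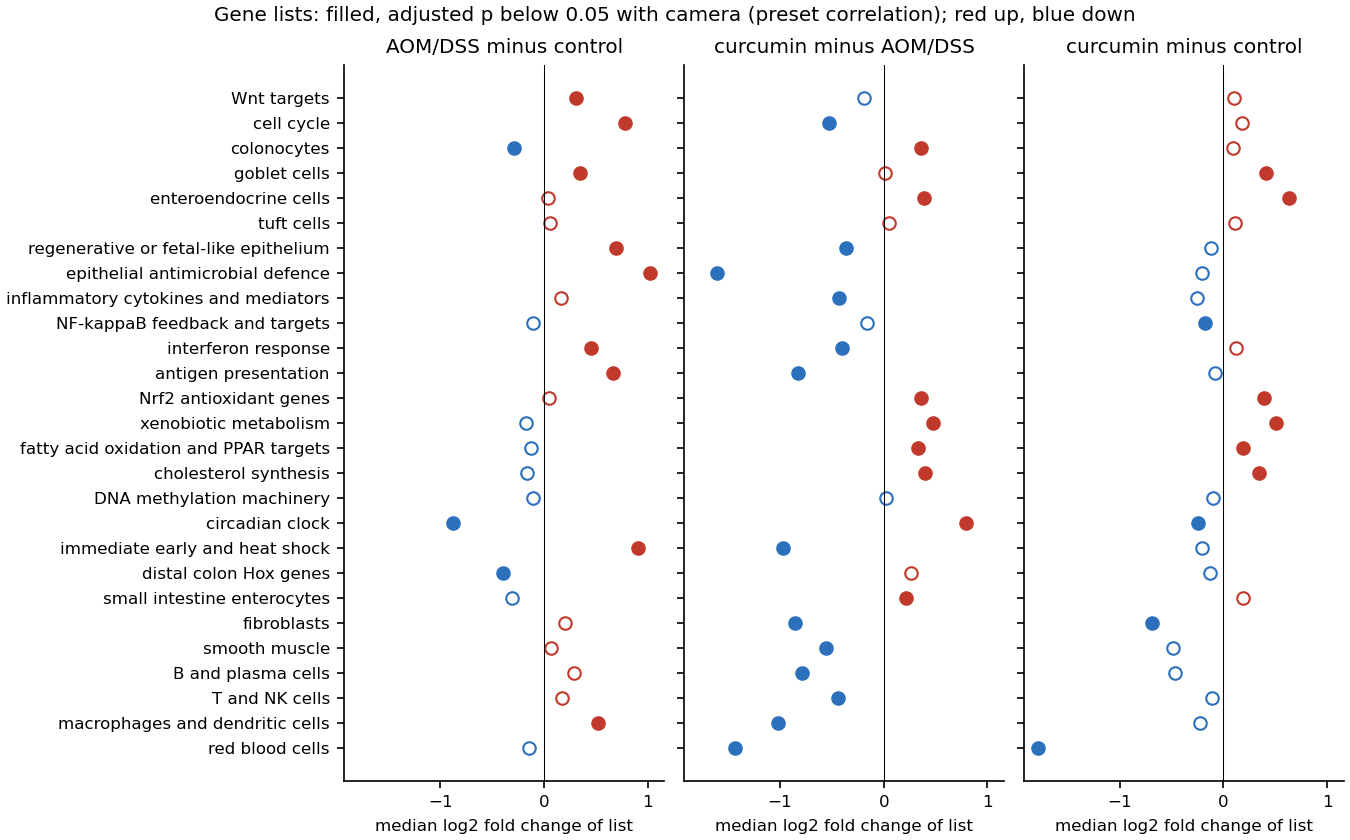
Median log2 fold change of each of the 27 tested gene lists in the 3 comparisons, filled where the camera adjusted p with the preset correlation was below 0.05, red for up and blue for down. With an estimated correlation 0 of the filled points keep that call, the lowest adjusted p being 0.0516, for the clock list in AOM/DSS against control.

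By limma 88 genes were higher and 42 lower with curcumin than in AOM/DSS, 1.08% of those tested, and 1742 had an unadjusted p below 0.05. Over all tested genes the libraries of both groups did not overlap for 1111 (9.22%), where chance gives 2.86%. Within the AT-rich and the GC-rich libraries Cd177 changed by -1.67 and -2.52 and Cbr3 by 2.12 and 2.28. A GC covariate gave 178 and 94, array weights 270 and 198, and leaving out curcumin replicate 2 gave 35 and 13. Of the 24 genes named by the rule, 13 stayed past the threshold whichever library was left out. The calls that ended were Ciart without curcumin 1 (adjusted p up to 0.05), E2f2 without curcumin 1 or 2 (adjusted p up to 0.0532), Adgrf1 without curcumin 1, 2 or 3 (adjusted p up to 0.0699) and Mir6381 without AOM/DSS 1 or curcumin 1 or 2 (adjusted p up to 0.0705), and, by number of libraries, Ckb in 5 of 12 (up to 0.102), Slc37a2 in 5 of 12 (up to 0.0935), Mt2 in 6 of 12 (up to 0.0974), Dbp in 8 of 12 (up to 0.124), Mt1 in 9 of 12 (up to 0.146), Hsph1 in 9 of 12 (up to 0.138) and Creb3l3 in 10 of 12 (up to 0.14).

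Curcumin against control asks what differed from the control libraries. Cbr3 was at 12.2 ± 1.98 FPKM in control and 82.3 ± 36.3 with curcumin (log2 fold change 2.55, SE 0.31, adjusted p = 0.00598), Tsku at 7.74 ± 2.27 and 33.5 ± 7.76 (log2 fold change 1.99, SE 0.23, adjusted p = 0.00598), and Nqo1, the quinone reductase of the Nrf2 response, at 16.9 ± 4.96 and 47.1 ± 12.3 (log2 fold change 1.42, SE 0.24, adjusted p = 0.0447). The aldo-keto reductases Akr1b8 (59.96 ± 28.1 to 181 ± 28.8, 1.67, adjusted p = 0.0356) and Akr1b7 (3.30 ± 0.974 to 9.77 ± 2.46, 1.33, adjusted p = 0.0386) also rose, the last with 27.2% of its exon bases shared with another gene. Fbxo32, a ubiquitin ligase, fell from 38.1 ± 3.68 to 18.4 ± 2.02 (log2 fold change -1.01, SE 0.12, adjusted p = 0.00598). Lyve1, of lymphatic endothelium, went from 4.66 ± 0.195 to 1.67 ± 0.292 (log2 fold change -1.09, SE 0.13, adjusted p = 0.00598). Pag1, a membrane adaptor (-1.10, adjusted p = 0.0356), Etl4 (-0.79, adjusted p = 0.0329) and Mylip, a ubiquitin ligase (-0.67, adjusted p = 0.0441), fell as well. Lyve1 (-0.85), Fbxo32 (-0.74) and Pag1 (-0.86) were already lower in AOM/DSS than in control, while Cbr3 (0.35, adjusted p = 0.683) and Tsku (-0.0081, adjusted p = 0.992) did not pass there. Mt2 (59.3 ± 33.7 and 434 ± 165, 3.02, adjusted p = 0.0601), Duox2 (18.8 ± 1.53 and 7.77 ± 2.16, -1.20, adjusted p = 0.0521) and Cd177 (14.9 ± 3.76 and 33.6 ± 6.83, 1.13, adjusted p = 0.0755) fell short of the threshold. Hmox1 (0.52, adjusted p = 0.359), Nos2 (-0.71, adjusted p = 0.26), Mki67 (0.31, adjusted p = 0.771), Lgr5 (-0.0043, adjusted p = 0.996), Axin2 (-0.13, adjusted p = 0.878) and Car1 (0.45, adjusted p = 0.747) did not pass either.

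The Nrf2 list rose against control (median log2 fold change 0.39, camera adjusted p = 8.02e-12). For Nrf2 antioxidant genes this p was 0.0725 with estimated correlation. Of its 27 members, 2 rose and 0 fell over all genes, against 10 and 0 over the list alone. Past the threshold were Cbr3 and Nqo1, with Me1 (1.54, adjusted p = 0.101) and Gsta3 (0.99, adjusted p = 0.204) next. Xenobiotic metabolism genes rose as a list (median log2 fold change 0.51, camera adjusted p = 0.000241), with 0 of 26 past the threshold over all genes and 3 over the list alone. For xenobiotic metabolism this p was 0.598 with estimated correlation. Cyp2c55 was at 144 ± 131 and 461 ± 119.6 FPKM (2.07, adjusted p = 0.351) beside Ces1f (1.73, adjusted p = 0.121), Aldh1a1 (1.54, adjusted p = 0.349) and Ces1g (1.36, adjusted p = 0.46). Fatty acid oxidation genes rose as a list (median log2 fold change 0.19, camera adjusted p = 0.00101; 0 of 21 over all genes, 1 over the list alone), with Angptl4 (1.11, adjusted p = 0.252), Pdk4 (1.00, adjusted p = 0.399) and Fabp2 (0.91, adjusted p = 0.522). For fatty acid oxidation this p was 0.514 with estimated correlation. Cholesterol synthesis genes rose as a list (median log2 fold change 0.35, camera adjusted p = 0.000301; 0 of 17 over all genes, 5 over the list alone), with Mvd (0.77, adjusted p = 0.24), Fdps (0.61, adjusted p = 0.134) and Nsdhl (0.58, adjusted p = 0.112). For cholesterol synthesis this p was 0.49 with estimated correlation, and the median 0.22 without control 1. Goblet cell genes rose as a list (median log2 fold change 0.41, camera adjusted p = 0.000174; 0 of 16 over all genes, 4 over the list alone). For goblet cells this p was 0.459 with estimated correlation. Muc2 was at 217 ± 22.2 and 441 ± 89.3 FPKM (1.00, adjusted p = 0.114), with Spink4 (0.68, adjusted p = 0.234), Retnlb (0.74, adjusted p = 0.776) and, below 0, Sytl2 (-0.68, adjusted p = 0.57). Enteroendocrine genes rose as a list (median log2 fold change 0.63, camera adjusted p = 0.0126; 0 of 13 over all genes, 3 higher and 1 lower over the list alone), with Insl5 (1.38, adjusted p = 0.247), Pyy (1.34, adjusted p = 0.267), Gcg (1.31, adjusted p = 0.232) and Tac1 (-1.38, adjusted p = 0.278). For enteroendocrine cells this p was 0.514 with estimated correlation.

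NF-kappaB targets fell as a list against control (median log2 fold change -0.18, camera adjusted p = 0.0126), with 0 of 13 past the threshold over all genes and 1 lower over the list alone. For NF-kappaB feedback and targets this p was 0.49 with estimated correlation, and the median -0.31 without curcumin 0. Without curcumin 2 or 3 the call ended (adjusted p = 0.0749 and 0.0756). Tnfaip3 was at 29.8 ± 3.42 and 18.7 ± 2.56 FPKM (-0.65, adjusted p = 0.119), Bcl3 (-0.53, adjusted p = 0.538), Birc3 (-0.37, adjusted p = 0.436) and Nfkbiz (-0.37, adjusted p = 0.537) following. Clock genes fell as a list (median log2 fold change -0.25, camera adjusted p = 0.034; 0 of 14 over all genes, 1 lower over the list alone), with Bhlhe40 (-0.39, adjusted p = 0.179), Nr1d1 (-0.38, adjusted p = 0.468), Clock (-0.37, adjusted p = 0.491) and Npas2 (-0.34, adjusted p = 0.527). For circadian clock this p was 0.49 with estimated correlation, and the median -0.14 without control 0, -0.12 without control 3 and -0.16 without curcumin 2. Without control 0 or 3 or curcumin 2 or 3 the call ended (adjusted p = 0.124, 0.108, 0.102 and 0.0756). Fibroblast genes fell as a list (median log2 fold change -0.69, camera adjusted p = 0.034; 0 of 8 in either adjustment), with Dcn (-1.06, adjusted p = 0.459), Postn (-0.79, adjusted p = 0.556), Dpt (-0.77, adjusted p = 0.527) and Sparc (-0.70, adjusted p = 0.641). For fibroblasts this p was 0.615 with estimated correlation, and the median -0.44 without control 0, -0.46 without control 2 and -1.05 without control 3. Without control 0 or 2 or curcumin 1, 2 or 3 the call ended (adjusted p = 0.213, 0.217, 0.0829, 0.0618 and 0.0769). Globin genes fell as a list (median log2 fold change -1.78, camera adjusted p = 0.000642; 0 of 5 over all genes, 5 over the list alone). For red blood cells this p was 0.49 with estimated correlation. Hbb-b1 was at 47.4 ± 36.2 and 9.56 ± 1.48 FPKM (-1.84, adjusted p = 0.355). The other 17 tested lists did not pass, with camera adjusted p from 0.0775 (B and plasma cells, median -0.47) to 0.739 (colonocytes, 0.092). Lists with too few members for a test, given as members and median log2 fold change, were matrix remodelling (3, 0.27), endothelium (2, -0.23), neutrophils (2, -0.079), mast cells (4, 0.056), enteric neurons and glia (1, -0.35) and adipocytes (3, 0.38).

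By limma 11 genes were higher and 6 lower with curcumin than in control, 0.141% of those tested, with an unadjusted p below 0.05 for 1468. Over all tested genes the libraries of both groups did not overlap for 996 (8.26%), where chance gives 2.86%. The AT-rich and the GC-rich libraries alone called 0 genes in either direction, while Cbr3 changed by 2.13 and 2.80 within them. A GC covariate gave 24 and 16, array weights 204 and 287, and leaving out control replicate 0 gave 2 and 2. Of the 10 genes named by the rule, Cbr3, Tsku, Lyve1 and Fbxo32 stayed past the threshold whichever library was left out. The others, by number of libraries whose removal ended the call, were Akr1b8 in 7 of 12 (up to 0.131), Nqo1 in 8 of 12 (up to 0.166), Akr1b7 in 8 of 12 (up to 0.119), Pag1 in 7 of 12 (up to 0.131), Etl4 in 6 of 12 (up to 0.12) and Mylip in 9 of 12 (up to 0.166).

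Setting both comparisons side by side asks which AOM/DSS changes were opposed with curcumin. Of the 153 genes that differed between AOM/DSS and control, 53 (34.6%) also differed between curcumin and AOM/DSS by limma, each with the opposite sign. Of these, 17 rose with AOM/DSS and were lower with curcumin, and 36 fell and were higher, while 0 changed the same way in both. The 10 named by the rule were Dbp, Ciart, S100g, Cd177, Cyp2d12, Slc37a2, Ifi47, Fxyd4, Tef and E2f2. Fxyd4 was at 226 ± 63.7, 49.9 ± 21.6 and 149.9 ± 40.2 FPKM in control, AOM/DSS and curcumin (-2.23, then 1.65, adjusted p = 0.0321), and Cyp2d12 at 80.6 ± 31.9, 21.4 ± 8.80 and 95.6 ± 20.3. E2f2 was at 1.75 ± 1.32, 7.39 ± 1.75 and 1.75 ± 0.333, and Ifi47 at 2.19 ± 0.876, 10.8 ± 3.83 and 2.57 ± 0.957. Other genes that differed with AOM/DSS missed the threshold with curcumin, among them Plet1 (12.9 ± 5.83 FPKM, -1.38, adjusted p = 0.111) and Lpo (5.74 ± 2.25, -0.96, adjusted p = 0.149). Fxyd4 (5 of 12 leave-outs, adjusted p up to 0.111) lost the call without 1 library.

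Both comparisons use the same AOM/DSS libraries, which alone makes their chance values opposite. Independent lists of these lengths would share 0.192 genes that rose and were then lower and 0.716 that fell and were then higher, leaving the sharing out. Across genes, which are not independent replicates, fold changes correlated at r = -0.616 against -0.544 in 100 simulated draws with no effect, and their covariance was -0.0696 against -0.0260, a difference of -0.0435. The share of all genes with opposite signs was 66.8%, against 68.6% simulated. With separate AOM/DSS libraries for each comparison, 2 in each, the 6 assignments gave between 6 and 14 genes in opposite directions, where independent lists would share between 0.0883 and 0.699, and r between -0.387 and -0.0756. The count was 80 with a GC covariate, 116 with array weights and 22 without curcumin 1.

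**Figure D4:**
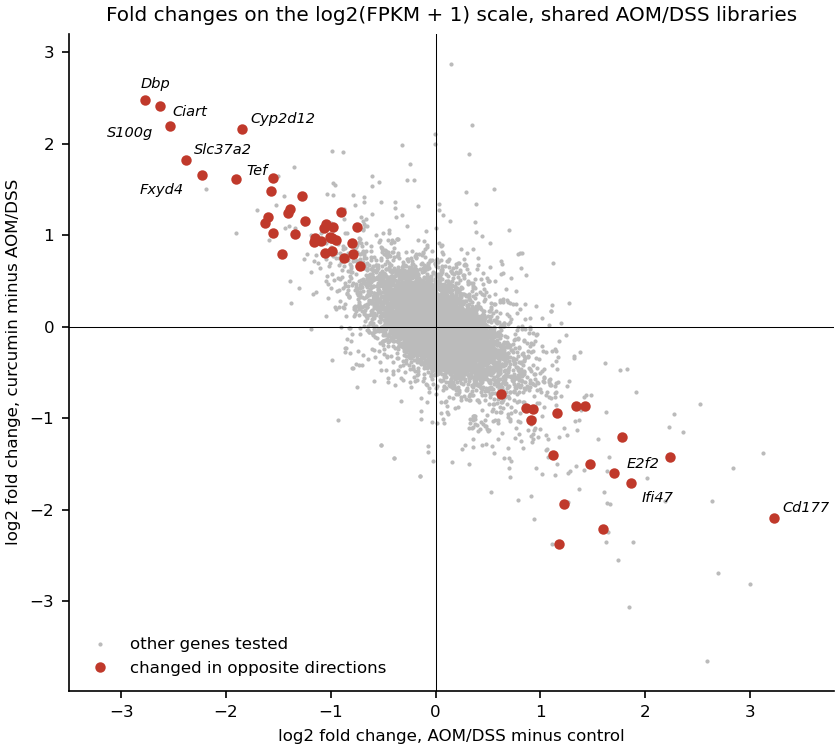
Log2 fold change of each tested gene in AOM/DSS minus control (x axis) and curcumin minus AOM/DSS (y axis), with the 53 genes past the threshold in both in red and the 10 largest named. The shared AOM/DSS libraries tilt the grey cloud downwards by themselves (simulated r = -0.544, observed -0.616).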

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

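All tests of explanations in this part, and the splits of the libraries, were chosen only after the results were seen. Within groups of 4 libraries, 45 of 531 groups of named genes held a value far from the other 3, where chance gives about 1 in 20, or 26.6. A value was taken as far from the rest where its gap to the nearest, over the range of the group, exceeded the 95% critical value of Dixon for 4 values. These values fell in 37 genes, and 15 of them, each the highest of its group, were in AOM/DSS replicate 3. That library held interferon genes high, with Ifit1 at 26.9 FPKM against 4.11 to 6.06 in the other 3. Ifit2 was at 12.4 against 0.465 to 2.25, Usp18 at 8.96 and Isg15 at 47.6. Also high there were Cxcl5 at 12.4, Sparc at 11.4, Dcn at 6.65, Fbln1 at 4.75, Acta2 at 6.48 and Myl9 at 4.82 FPKM. So were Jchain at 53.04, Slc10a2 at 55.5, Me1 at 6.53, Ptgs2 at 0.323 and Cyp1a1 at 0.0721.

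Control replicate 1 stood apart for secretory, defence and metabolic genes, with Retnlb at 102, Ang4 at 334, Reg3b at 323, Sytl2 at 55.7 and Ces1g at 4.13 FPKM. AOM/DSS replicate 0 stood apart for a pair of chaperones and a carnitine carrier, with Hspa1a at 214, Hspa1b at 289.8 and Slc25a20 at 94.6 (lowest) FPKM. In AOM/DSS replicate 1 the distant values were Duox2 at 71.5 and Tac1 at 42.6 FPKM, and in replicate 2 Hbegf at 30.8 and Pyy at 36.8 (lowest) FPKM. Curcumin replicate 0 had Duoxa2 at 18.7, Car4 at 1702, Pyy at 247, H2-Eb1 at 17.1, Jchain at 8.44 and Postn at 1.49 FPKM. The other curcumin libraries had Per3 at 13.2 in replicate 1, Ptgs2 at 0.0449 in replicate 2 and Cyp1a1 at 0.0216 and Reg3b at 267 in replicate 3. Among controls, replicate 0 had Cyp1a1 at 0.0349, H2-DMb1 at 9.61 and H2-DMa at 7.27 FPKM, replicate 2 had Fbxo32 at 32.5 (lowest), Isg15 at 7.78 (lowest), Tac1 at 33.1 and Ccl20 at 18.5, and replicate 3 had Gjb5 at 44.1.

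The 12 libraries split by gene GC content, in a way that follows treatment only in part, since each group has libraries of both kinds. If the GC trend were the whole cause of the calls, they should end once the trend is removed from each library, yet 138 of the 153 calls between AOM/DSS and control and 127 of the 130 between curcumin and AOM/DSS stayed past the threshold with their sign, which argues against it as the whole cause. The cause of the split stays open, as the labels give no batch or date, and a smaller share in the size of single changes is not excluded.

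Clock genes were shifted in the AOM/DSS libraries. Split after the fact into members that peak with Dbp (8 genes, mean change -1.62) and with Arntl (4 genes, mean change 0.50), the arms differed by -2.12 between AOM/DSS and control and by 1.99 between curcumin and AOM/DSS. A lower share of epithelial cells should lower colonocyte genes by about as much, but their median change was -0.29 (SD 0.69) against -1.43 for the Dbp arm, and GC bias is argued against by 6 of 6 called clock genes staying past the threshold once the trend was removed. Another time of day at collection, which moves these arms apart, cannot be told apart from an effect of AOM/DSS, since the labels give no collection times; per library the arm difference ran from -2.66 to -0.026 in AOM/DSS and from 0.077 to 1.13 in control. An effect of AOM/DSS on the clock may also be present and was not tested.

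Cd177 was higher in all 4 AOM/DSS libraries (203, 156, 117 and 117 FPKM) than in any control. Neutrophils carry far more S100a8 and S100a9 than Cd177. The sum of both reached at most 0.0775 of Cd177 in these libraries (S100a8 at 5.64 FPKM or less). This argues against neutrophils as main Cd177 source. GC bias is argued against by a log2 fold change of 3.16 after the trend was removed (SE 0.22, limma adjusted p = 3.84e-05), against 3.23 before. Higher Cd177 in epithelial cells is an untested hypothesis, as are other cell sources.

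Other splits of the same libraries were counted beside the numbers of called genes. For AOM/DSS against control, 1 of 35 splits gave as many as the real 153, and the highest other split gave 144. That split exchanged replicate 2 of both groups, and the next gave 13. Cell cycle genes go with an exchange of these labels (mean log2 deviation 0.449 in control replicate 2 and -0.283 in AOM/DSS replicate 2), while clock genes (0.193 and -0.739) and Cd177 (19.2 and 117 FPKM) go against it, and it stays open. For curcumin against AOM/DSS 2 of 35 splits gave as many as the real 130, so chance cannot be excluded from the count alone. The other split gave 1033 and parted replicates 0 and 1 from 2 and 3, which is the GC split and points to a structure of the samples. With the GC group as a covariate, 1 of 35 splits gave as many as the real 272, the highest other split giving 0. The same covariate gave 238 genes for AOM/DSS against control, where 2 of 35 splits gave as many and the highest other, again with replicate 2 exchanged, gave 357. Chance is thus not excluded from the counts in either of these comparisons. For curcumin against control, 1 of 35 splits gave as many as the real 17 and the highest other 0, and with the covariate 1 of 35 gave as many as the real 40 and the highest other 1. For that count the share was 0.0286, the smallest that 35 splits allow and not adjusted for the 6 counts made. Chance is therefore not excluded for it, nor for the distance between these groups (exact permutation p = 0.0571).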

How the results depend on the processing

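Chosen after seeing the data were the GC covariate, the removal of the GC trend, voom on recovered reads and the fits of GC-rich or AT-rich libraries alone; the other alternatives were fixed beforehand. Counts below are higher/lower for AOM/DSS against control, curcumin against AOM/DSS and curcumin against control (55/98, 88/42 and 11/6 by default), then genes in opposite directions (53), and only values that moved by over 1.5 times are given; the cause was not tested except where stated. A pseudocount of 0.1 gave 6 higher in the last comparison, no filter 4/3 there, a filter of 5 FPKM 11 lower, rescaling to a common sum 7 higher, quantile scaling 11 lower and voom 12 lower. A required fold of 2 gave 35/43, 50/19 and 7 higher, by construction. Fits of only the 2 groups compared gave 21/33 and 26 lower, with fewer libraries behind the spread. Array weights gave 98/190, 270/198, 204/287 and 116, with weights of 4.13 and 2.93 for curcumin replicates 2 and 3. The GC covariate gave 86/152, 178/94, 24/16 and 80, and removal of the GC trend 154 lower, 163/76 and 14 lower. AT-rich libraries alone gave 4/0, 0/1, 0/0 and 0, and GC-rich libraries alone 5/2, 5/3, 0/0 and 3, with 7 and 5 libraries. In the GC-rich libraries alone the camera direction of 5 lists reversed between AOM/DSS and control. Their medians there were -0.24 (Wnt targets), -0.0686 (interferon), -0.49 (antigen presentation), 0.13 (distal Hox) and 0.0306 (macrophages). The macrophage median thus stayed above 0, as in the main fit. In that fit 1 control library is assumed to vary like the other groups.

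The replicate block gave 32/50 genes for AOM/DSS against control, 26 lower for curcumin against AOM/DSS, 2/0 for curcumin against control and 31 in opposite directions. In the last comparison Cbr3 stayed past the threshold with the block, while Tsku, Lyve1 and Fbxo32 did not. Of 12 pairs of libraries with the same number, 6 had deviations that correlated above 0.1 across genes, from r = -0.333 to 0.456, so the numbers were not taken to pair the samples. For AOM/DSS and curcumin the correlations were 0.0362, 0.350, 0.301 and 0.357 for replicates 0 to 3, but there the number follows the GC group. Libraries correlated best with their own number in 2, 3 and 3 of 8 in the 3 comparisons.

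The distance between groups passed its exact permutation test (p = 0.0286) for AOM/DSS against control with quantile scaling (5.39), without the GC trend (5.64) and without AOM/DSS 0, 1 or 2, for curcumin against AOM/DSS with a pseudocount of 0.1 (8.55), no filter (7.69), without the GC trend (9.05) and without AOM/DSS 1, 2 or 3, and for curcumin against control without the GC trend (6.00) and without control 0. Without any other single library it did not pass (exact p from 0.0571 to 0.2). Leaving out single libraries moved it between 2.18 (control 3) and 8.44 (AOM/DSS 2), between 4.69 (curcumin 2) and 9.96 (AOM/DSS 0), and between 2.602 (curcumin 1) and 7.27 (control 0). Without single libraries the counts ranged from 23 to 79 higher and 30 to 122 lower, 35 to 101 and 13 to 51, and 2 to 17 and 2 to 18, with 22 to 60 in opposite directions. Those moved by over 1.5 times were, by the library left out, 29/47 control 0, 23/30 control 3, 36/47 AOM/DSS 0, 30/49 AOM/DSS 3, 36/63 curcumin 1, 34/58 curcumin 2 and 36/61 curcumin 3 for AOM/DSS against control, 57/51 AOM/DSS 0, 38/23 curcumin 0, 38/14 curcumin 1, 35/13 curcumin 2 and 56/26 curcumin 3 for curcumin against AOM/DSS, 2/2 control 0, 6/4 control 1, 3/2 control 3, 17/18 AOM/DSS 1, 4/3 AOM/DSS 2, 2/2 curcumin 0, 3/2 curcumin 1, 3/2 curcumin 2, 6/3 curcumin 3 and 9/13 control 2 for curcumin against control, and 34 control 3, 34 AOM/DSS 0, 26 curcumin 0, 22 curcumin 1, 23 curcumin 2 and 29 curcumin 3 in opposite directions.

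Of 91 calls of named genes, leaving out 1 library ended between 9 (AOM/DSS 1) and 35 (curcumin 2), a GC covariate 1, no trend 5, voom 6, no filter 30, the block 30, the 2 groups alone 32, GC-rich libraries alone 80 and AT-rich libraries alone 87, and 0 changed sign. All 43 list calls ended with estimated correlation. With GC-rich libraries alone 13 ended and 5 more reversed in camera direction, not all in median. AT-rich libraries alone ended 5, voom 0 and other processing 0 to 4 of those still testable. Leaving out 1 library ended 1 to 7 (AOM/DSS 3). The sizes of the libraries limit low genes: 1 read is worth more FPKM in control replicate 1, the smallest at 5567988 reads, than in the other 11.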

Other observations

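Of the 53 genes that changed in opposite directions, 5 beyond those named by the rule are given here, chosen after their values were seen. Slc6a4, the serotonin transporter, was at 23.5 ± 7.66 FPKM in control, 8.09 ± 2.15 in AOM/DSS and 20.01 ± 1.38 with curcumin (log2 fold change -1.40, SE 0.23, adjusted p = 0.00994, then 1.24, adjusted p = 0.02). Slc2a5, the fructose transporter, went the same way (-1.38, adjusted p = 0.0143, then 1.28, adjusted p = 0.0221) and the desaturase Scd1 the other way (0.93, adjusted p = 0.0176, then -0.90, adjusted p = 0.0204). Slc2a5 (without control replicate 3, adjusted p up to 0.0615) and Scd1 (without control replicate 3, adjusted p up to 0.0615) lost the call without 1 library. Against AOM/DSS, Slc6a4 (4 of 12 leave-outs, adjusted p up to 0.0625), Slc2a5 (5 of 12 leave-outs, adjusted p up to 0.0686) and Scd1 (without curcumin replicates 0, 1 or 2, adjusted p up to 0.07) lost theirs.

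Cipc, a partner of the Clock protein, was at 64.4 ± 9.61 FPKM in control, 30.4 ± 1.64 in AOM/DSS and 54.2 ± 6.60 with curcumin (-1.05, adjusted p = 0.00274, then 0.81, adjusted p = 0.00933). Nfil3 went the other way (1.12, adjusted p = 0.0469, then -1.41, adjusted p = 0.0157). Its limma call against control ended in 11 of 12 leave-outs (adjusted p up to 0.164), and the one with curcumin without curcumin replicates 0 or 1 (adjusted p up to 0.0561).

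No pair of libraries was close enough for a duplicate: the smallest chi-square per degree of freedom between the reads of any pair was 8.004, for curcumin replicates 2 and 3.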
